A study of Mus musculus with 43 samples.

How the data were processed

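RNA of 43 frozen mouse mammary tumours was measured on 1 Affymetrix array each; per the labels, 100 ng of total RNA extracted with Trizol was converted to biotinylated cRNA following a kit protocol named for 3' IVT labelling, while the annotation of the probe sets is that of a Mouse Gene 2.0 ST type array. The authors supplied log2 values that they had made from the scanned intensities with RMA (background correction, quantile normalization and summary by probe set), software version not stated. These deposited log2 values were used as they stood. They ran from 2.17 to 14.17, the median of an array lay between 6.9 and 7.04, and a given quantile differed between arrays by at most 0.32. Intensities of arrays give no count of molecules, and the number of arrays limits the precision. The labels give no scan date or batch, so array handling could not be examined.

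The table held 41345 probe sets. Of these 23521 matched 1 gene, 1820 matched several genes and 16004 had no gene listed, and the last 2 kinds were not used for named genes. The 23521 probe sets covered 22180 genes, and where a gene had more than 1 probe set (1082 genes) the one of highest mean was taken. Genes above the 30th percentile of the table (5.98) in at least 9 arrays were kept, which left 17934. The p53 gene itself (Trp53) had no probe set of its own and was not analysed here.

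Groups followed the labels: sham (9), SIR (15; 10, 50 and 100 cGy of gamma rays, 7, 4 and 4 tumours) and DIR (19; 14 Ar at 49 cGy and 5 Si at 30 cGy). An iron ion exposure and a larger sham group named in the description of the series had no further sample, and 0 columns of the table were left unmapped. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with group means only and 1 shared estimate of spread from all 43 arrays for SIR against sham, DIR against sham, DIR against SIR and the mean of SIR and DIR against sham. Si was compared with Ar in the 19 DIR arrays, and a slope per 10 cGy was fitted in the 15 SIR arrays. The p-values were adjusted after Benjamini and Hochberg over the genes tested, with a threshold of 0.05. All tests are two-sided.

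Before the data were examined, 33 gene lists (721 genes, 664 measured) were written down. The immune lists were T cells, cytotoxic T and NK cells, immune checkpoints and regulatory T cells, B cells, plasma cells and immunoglobulins, macrophages, neutrophils and granulocytic myeloid cells, dendritic cells, mast cells, MHC class II presentation, MHC class I presentation, interferon response, and inflammation and COX-2. The epithelial lists were luminal epithelium, hormone-sensing luminal cells, alveolar and milk genes, basal and myoepithelial cells, and keratinocyte and squamous genes. Other cells were covered by fibroblasts and extracellular matrix, endothelium, adipocytes, skeletal muscle and red blood cells. The remaining lists were proliferation, DNA damage response and repair, p53 target genes, epithelial-mesenchymal transition, the TGF-beta, Notch and Wnt pathways, hypoxia and glycolysis, oxidative phosphorylation, and immediate early and heat shock genes. Tumour cells of mammary origin also express the genes of the epithelial lists. A tumour's score for a list was the mean, over its measured genes, of the log2 value minus that gene's mean over the 43 arrays. Differences of mean scores were tested by permuting tumour labels, with full enumeration where a group had fewer than 10 tumours and for dose (1307504 assignments for SIR against sham, 6906900 for DIR against sham) and with 100000 resamples otherwise, and adjusted over the 33 lists. Genes of a list were also adjusted over the list alone. As other tests of the lists, camera with a preset correlation of 0.01 or an estimated one and fry were run in limma; fry asks whether the genes of a list move one way on balance and does not compare them with other genes. Spread between tumours, the relation of the proliferation score to 13 immune scores and the share of variance between groups (pseudo-F) were tested by permutation with 100000 resamples (numpy 2.4.6, scipy 1.17.1, Python 3.11.15).

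Genes were chosen for mention by a rule fixed at the same time as the lists: all genes that passed where fewer than 10 did, the 5 genes of smallest unadjusted p on each side that did not pass (3 for the mean of SIR and DIR, Si against Ar and dose), up to 4 members of smallest p of each list described member by member, and 16 measured genes fixed by name for the 3 comparisons of sham, SIR and DIR. The genes described for the 5 tumours of low luminal score, and the genes whose highest values all lay in sham tumours, were chosen after their values were seen.

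The gene test was tested on simulated data with 200 of 17934 genes changed per comparison. At a log2 change of 1 it recovered 94% for SIR against sham, 88% for DIR against sham, 82% for DIR against SIR, 68% for Si against Ar and, over the dose range, 72% for dose, with 7 or 8 false calls in each. The list test recovered 5 of 5 lists shifted by 2 SD, with 1 false call in DIR against sham and 0 in the others. Both simulations drew each gene or list independently from normal values, with the same SD in all groups. Real genes vary together and differ in spread between groups, so these shares do not measure the power in the real data. The alternatives tried were other filters on low values, all probe sets of a gene or each probe set on its own, quantile normalization again, subtraction of the array median, other variance models, array weights, a replicate block, the first principal component as a covariate, subsets of the arrays, scores from scaled genes or medians, and each array left out in turn. Added after the data were seen were DIR 3 and DIR 5 averaged as 1 tumour, SIR 2 left out of the correlations, and the 5 tumours of low luminal score left out.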

Results

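Gene expression was measured in 43 mammary tumours that arose from p53-null mammary epithelium after transplantation into BALB/c host mice, so that the hosts were exposed to radiation while the transplanted epithelium was not. The hosts were sham-irradiated (9 tumours) or received whole-body sparsely ionizing gamma rays (SIR, 15 tumours) or densely ionizing ions (DIR, 19 tumours). Within SIR, 7 tumours came from hosts given 10 cGy, 4 from hosts given 50 cGy and 4 from hosts given 100 cGy. Within DIR, 14 tumours came from hosts given 49 cGy of argon ions (Ar, tumours DIR 1 to DIR 14) and 5 from hosts given 30 cGy of silicon ions (Si, tumours DIR 15 to DIR 19). Each tumour was hybridized to 1 array, the median log2 intensity of an array lay between 6.9 and 7.04, and the number of arrays limits the precision. Of 22180 genes measured, 17934 passed the filter on low values and were tested. Tumours differed far more within the groups than between them: the 3 host groups accounted for 6.31% of the variance over all tested genes, against 4.76% given by chance (pseudo-F = 1.35, permutation p = 0.0691). DIR 3 and DIR 5 had nearly the same values (Pearson r across genes 0.9947, next highest pair of arrays 0.9757); they are counted as separate tumours, as the labels list them. In 5 irradiated tumours (SIR 8, SIR 15, DIR 1, DIR 7 and DIR 19) the luminal epithelium score lay at or below -2.1, against -0.77 or more in the others. The p-values given for genes and gene lists measure differences against the spread between tumours. For Gm13544, Map7d2, Bex2, 4933407L21Rik, Col28a1 and H2-DMb1 the lower group lay near the filter value of 5.98, so their log2 differences are differences of intensity and lower bounds in size. For Ly6g and Ubash3a the means of both groups lay below that value, and their differences describe intensities only. The same holds for the slopes of Ngp, Mcpt8 and Mcpt4, whose means at 100 cGy lay below it.

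The first comparison asked how tumours of hosts given sparsely ionizing gamma rays differed from those of sham-irradiated hosts. Gm13544, a long non-coding RNA gene (probe set 17370947), was lower in SIR tumours, with a mean log2 intensity of 6.01 ± 0.16 (SD, n = 15) against 6.92 ± 0.79 (SD, n = 9) in sham tumours, a log2 difference of -0.91 ± 0.16 (SE). All 15 SIR tumours lay below the sham mean, as did sham 4, sham 6, sham 7 and sham 9 (6.11 to 6.17). The SE came from 1 spread shared by all groups, while the SD was 0.79 in sham and 0.16 in SIR tumours. It therefore understates the error of this difference. The SIR intensities lay near the filter value of 5.98, so no fold is given and the difference is a lower bound in size. The next genes by p did not pass. Among them, Pex3, a peroxisome assembly factor, had a difference of +0.48, and Rmdn2, a microtubule regulator family member, one of +0.92, with all 15 SIR tumours above the sham mean for both. Tpt1, the translationally controlled tumour protein gene, Rp2 and Fbxo4 had differences of +0.46, +0.34 and +0.36. On the lower side stood Map7d2, a microtubule-associated protein of neurons, at -1.53, Lrrn1, a leucine-rich repeat protein of developing neurons, at -1.07, Bex2, a brain-expressed X-linked gene, at -0.92, Pou3f3, a neural transcription factor, at -0.90, and 4933407L21Rik at -0.35. For each of these 5 genes all 15 SIR tumours lay below the sham mean.

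Markers of infiltrating cells had higher means in SIR than in sham tumours, and none of these differences passed. All 21 tested macrophage genes had differences above 0, with Csf1r, the receptor for macrophage colony-stimulating factor, at +0.46, the macrophage antigen Adgre1 at +0.36, and the complement genes C1qb and C1qa both at +0.27. The macrophage score differed by +0.25 ± 0.16 (SE; exact permutation p = 0.141, adjusted 0.644; 11 of 15 tumours above the sham mean). All 16 T cell genes were also above 0, among them the co-receptor Cd4 at +0.42, Cd2 at +0.25, the T cell receptor component Cd3d at +0.15 and the adaptor Lat at +0.19. Their score differed by +0.16 ± 0.13 (SE; exact permutation p = 0.285, adjusted 0.644; 8 of 15 tumours above the sham mean), and by +0.09 without SIR 9. For B cells, 13 of 15 genes lay above 0, with Bank1, a B cell scaffold protein, at +0.71, Cd22 at +0.45, Cd37 at +0.44 and the chemokine receptor Cxcr5 at +0.32. The B cell score differed by +0.37 ± 0.25 (SE; exact permutation p = 0.247, adjusted 0.644; 8 of 15 tumours above the sham mean), and by +0.20 without SIR 9. Fibroblast and extracellular matrix genes showed the widest difference of the 33 lists on the higher side, +0.43 ± 0.23 (SE; exact permutation p = 0.0538, adjusted 0.644; 12 of 15 tumours above the sham mean). Of its members, the matrix proteoglycan-binding protein gene Dpt stood at +1.01, fibroblast activation protein Fap at +0.60, collagen Col6a1 at +0.59 and the pericyte receptor Pdgfrb at +0.48. Endothelial genes all lay above 0 as well (22 of 22), with a score difference of +0.23 ± 0.14 (SE), or +0.15 without sham 4.

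Proliferation genes lay on the other side of 0 in SIR tumours, 30 of 31 of them below it, with the mitotic kinase Cdk1 at -0.72, the spindle motor Kif11 at -0.42, the checkpoint kinase Ttk at -0.38 and thymidylate synthase Tyms at -0.26. The proliferation score differed by -0.21 ± 0.19 (SE; exact permutation p = 0.346, adjusted 0.644; 9 of 15 tumours below the sham mean), and by -0.10 without SIR 2. Within SIR the proliferation score rose with dose (slope +0.059 per 10 cGy, not passing). In the means, the difference from sham lay mainly with the 10 cGy tumours, among them SIR 2 at -1.75 (next -0.53). This placing was not tested. In the hormone-sensing luminal list Greb1, an estrogen receptor target, fell by 0.65 when adjusted over the list alone (1 of 14 members), while the progenitor marker Prom1 stood at -0.64, the estrogen receptor co-activator Cited1 at -0.21 and the calcium-binding protein gene S100a6 at +0.28. The Wnt transcription factor Lef1 fell by 1.53 and the ligand Wnt3 by 0.26 when adjusted over the list alone (2 of 27 members of the Wnt list), and the receptors Lgr6 and Lgr5 stood at -0.95 and +0.52. Score differences were -0.22 ± 0.29 (SE) for the hormone-sensing list (-0.12, -0.11 and -0.09 without sham 1, sham 7 and sham 8) and -0.14 ± 0.09 (SE) for the Wnt list (-0.09 without sham 9). Over all lists, 0 genes rose and 3 fell when adjusted over the list alone, against 0 list genes when adjusted over all genes. None of the genes fixed in advance passed. The prostaglandin synthase Ptgs2 (COX-2) stood at +0.81, the progesterone receptor Pgr at -0.48 and the luminal keratin Krt8 at +0.40. The checkpoint ligand Cd274 (PD-L1) stood at +0.30, the cell cycle inhibitor Cdkn1a (p21) at -0.28 and the T cell gene Cd3e at +0.26. Smaller values were those of the proliferation antigen Mki67 at -0.24, the cytokine Tgfb1 at +0.15, the estrogen receptor Esr1 at +0.14, the regulatory T cell factor Foxp3 at +0.10, the neutrophil antigen Ly6g at -0.06, the cytotoxic co-receptor Cd8a at +0.03 and the basal keratin Krt14 at +0.03.

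By limma, 1 gene differed between SIR and sham tumours (Gm13544, log2 difference -0.91, adjusted p = 0.0322, 15 of 15 tumours below the sham mean). For this gene the spread shared by all groups, which entered the p, was smaller than that among sham tumours alone. Unadjusted, 982 genes had a p under 0.05 (459 higher and 523 lower), where 897 were expected by chance. Without moderation of the variances, in a fit to the arrays of both groups alone, 0 genes passed. Gm13544 was also lost in that fit with moderation, so the part of moderation was not separated. Without the 5 tumours of low luminal score it was lost as well (log2 difference -0.92 there). It was lost too with part of the gamma doses, with the stricter filter, with every probe set tested and with the replicate block. Leaving out any 1 of sham 1, sham 2, sham 3, sham 5, sham 8, SIR 1, SIR 3, SIR 4, SIR 6, SIR 9, SIR 10, SIR 11, SIR 13 and SIR 15 gave a count of 0. Of the 33 lists 0 passed in the permutation test, and 0 had an unadjusted p under 0.05. The camera test of limma called 12 lists at a preset correlation of 0.01, none of which held with an estimated correlation (smallest adjusted p = 0.681), and fry called 0 (smallest adjusted p = 0.656).

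The comparison of DIR with sham tumours asked the same of densely ionizing radiation. Gm13544 was lower here too, at 6.04 ± 0.24 (SD, n = 19), a log2 difference of -0.88 ± 0.16 (SE), with all 19 DIR tumours below the sham mean. The intensities of the DIR tumours again lay near the filter value, so this too is a lower bound in size. No other gene passed, and 25 genes (9 higher, 16 lower) stood at an adjusted p under 0.1. With DIR 3 and DIR 5 averaged as 1 tumour that number was 1. The widest difference among the 10 nearest to passing was that of Dlx3, a homeobox factor of epidermis and placenta, at 8.32 ± 0.89 (SD, n = 19) against 10.36 ± 1.3 (SD, n = 9), a difference of -2.04 ± 0.42 (SE) seen in 18 of 19 tumours. Derl3, which works in the degradation of misfolded secretory proteins, stood at -1.49, the neuronal kinase Dclk2 at -1.08, the heparan sulfate proteoglycan Gpc2 at -0.92 and the endolysosomal channel Mcoln3 at -0.40. Above 0 stood the ETS-family factor Elk3 at +0.68, Pex3 at +0.50, the RNA-binding protein gene Rbms2 at +0.48, the cyclin-dependent kinase Cdk17 at +0.46 and the Golgi GTPase Arl1 at +0.34. None of these 10 genes passed (adjusted p = 0.0914 for each, 18 or 19 of 19 tumours on the side of the difference).

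**Figure D1:**
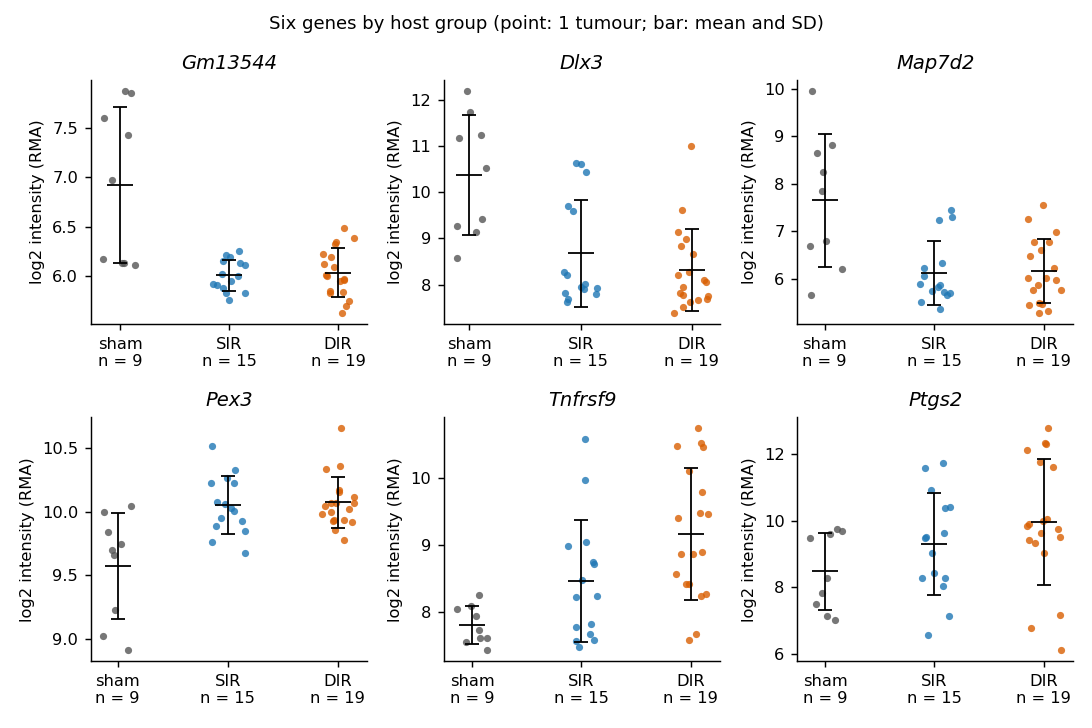
Log2 intensity (vertical axis, RMA values) of 6 genes in tumours of sham (n = 9), SIR (n = 15) and DIR (n = 19) hosts; each point is 1 tumour and bars give the mean and SD. Gm13544 exceeded 6.49, the highest irradiated tumour, in 5 sham tumours; of the 6 genes it was the one that passed at an adjusted p under 0.05, in both SIR and DIR.

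Genes of immune checkpoints and regulatory T cells formed the list nearest to the threshold in DIR tumours. Its score was 0.21 ± 0.06 (SE) above that of sham tumours, with 17 of 19 tumours above the sham mean, and did not pass (exact permutation p = 0.00232, adjusted 0.0765). Its widest difference was that of Tnfrsf9, a co-stimulatory receptor of activated T cells, with a log2 intensity of 9.17 ± 0.99 (SD, n = 19) against 7.8 ± 0.29 (SD, n = 9), a fold of 2.58. The exhaustion marker Havcr2 (TIM-3) stood at +0.57 and the regulatory T cell factor Ikzf2 (Helios) at +0.44, while Tnfrsf18 (GITR) stood at -0.45, and 10 of the 14 members lay above 0. When adjusted over the list alone, Tnfrsf9 rose and Tnfrsf18 fell. The T cell score itself differed by 0.04 ± 0.11 (SE), and Foxp3 by -0.05.

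Inflammatory genes had higher means in DIR tumours, 21 of 23 above 0, and their score was 0.51 ± 0.18 (SE) above that of sham tumours without passing (exact permutation p = 0.0275, adjusted 0.384; 15 of 19 tumours above the sham mean). Prostaglandin synthase Ptgs2 (COX-2) had a log2 intensity of 9.97 ± 1.89 (SD, n = 19) against 8.48 ± 1.15 (SD, n = 9), a fold of 2.8, and the downstream enzyme Ptges stood at +0.70. The neutrophil attractant Cxcl5 stood at +1.01, and the inducible nitric oxide synthase Nos2 rose by +0.96 when adjusted over the list alone (1 of 23 members). Genes of neutrophils and granulocytic myeloid cells were 0.40 ± 0.16 (SE) above sham (exact permutation p = 0.0349, adjusted 0.384; 15 of 19 tumours above the sham mean). In that list 5 of 20 members rose when adjusted over the list alone, among them the gelatinase Mmp9 at +1.63, the interleukin-1 decoy receptor Il1r2 at +0.91, the chemokine receptor Cxcr2 at +0.89 and the amplifying receptor Trem1 at +0.82. Without the 5 tumours of low luminal score, which had Ptgs2 between 10.91 and 12.78, the inflammation score was 0.40 and the neutrophil score 0.35 above sham. The nearly identical DIR 3 and DIR 5 had inflammation scores of 1.031 and 1.027 and neutrophil scores of 0.973 and 0.935. Only DIR 1 had higher ones, so counting the pair as 1 tumour would lower both differences. Mast cell genes were 0.27 ± 0.13 (SE) above sham (exact permutation p = 0.0799, adjusted 0.594; 13 of 19 tumours).

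Among 25 targets of p53, 3 rose when adjusted over the list alone: Mdm2, the ubiquitin ligase of p53, by +0.37 in 19 of 19 tumours, the apoptosome component Apaf1 by +0.46 and the translesion polymerase Polk by +0.37. The pro-apoptotic Pmaip1 (Noxa) stood at +0.38 and the score differed by 0.06 ± 0.06 (SE). The tumours arose from p53-null epithelium, so these values do not show p53 activity in the tumour cells, and their source was not tested. Basal and myoepithelial genes differed by -0.31 ± 0.26 (SE), and in that list the cytokine Il17b fell by 2.39 when adjusted over the list alone (1 of 22 members), while the basal transcription factor Trp63 stood at -1.02, the matrix protein gene Sparcl1 at -0.51 and the ligand Wnt10a at +0.64. Over all lists 11 genes rose and 5 fell when adjusted over the list alone, against 0 list genes when adjusted over all genes. The other genes fixed in advance did not pass either. Pgr stood at -0.56, Krt8 at +0.53, Krt14 at +0.35 and Esr1 at -0.29. Closer to 0 stood Cd274 at +0.28, Csf1r at +0.27, Cdkn1a at +0.25, Tgfb1 at +0.18, Adgre1 at +0.16, Ly6g at +0.16, Cd8a at -0.12, Cd4 at +0.09, Cd3e at -0.09 and Mki67 at -0.09.

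By limma, 1 gene differed between DIR and sham tumours (Gm13544, log2 difference -0.88, adjusted p = 0.0257, 19 of 19 tumours below the sham mean). The same limit of the shared spread applies here. Unadjusted, 2014 genes had a p under 0.05 (968 higher and 1046 lower), where 897 were expected. The count was 0 without sham 1, sham 2, sham 3, sham 5 or DIR 5, 86 without sham 4, 17 without sham 8, 14 without sham 7, 11 without sham 6, 3 without sham 9 or DIR 15 and 2 without DIR 17. Without moderation of the variances, in a fit to the arrays of both groups alone, 0 genes passed. The count was also 0 without the 5 tumours of low luminal score (Gm13544 at -0.87 there). Gm13544 was also lost with moderation in the arrays of both groups alone, so the part of moderation was not separated. It was lost too with Ar or Si arrays only, with the stricter filter and with the replicate block. Of the lists 0 of 33 passed by permutation, with 3 at an unadjusted p under 0.05 where 1.65 were expected. A single list, that of checkpoints and regulatory T cells, passed without DIR 11, DIR 13 or sham 4. The camera test called 10 lists at the preset correlation, none of which held with an estimated correlation (smallest adjusted p = 0.732), and fry called 0 (smallest adjusted p = 0.258).

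**Figure D2:**
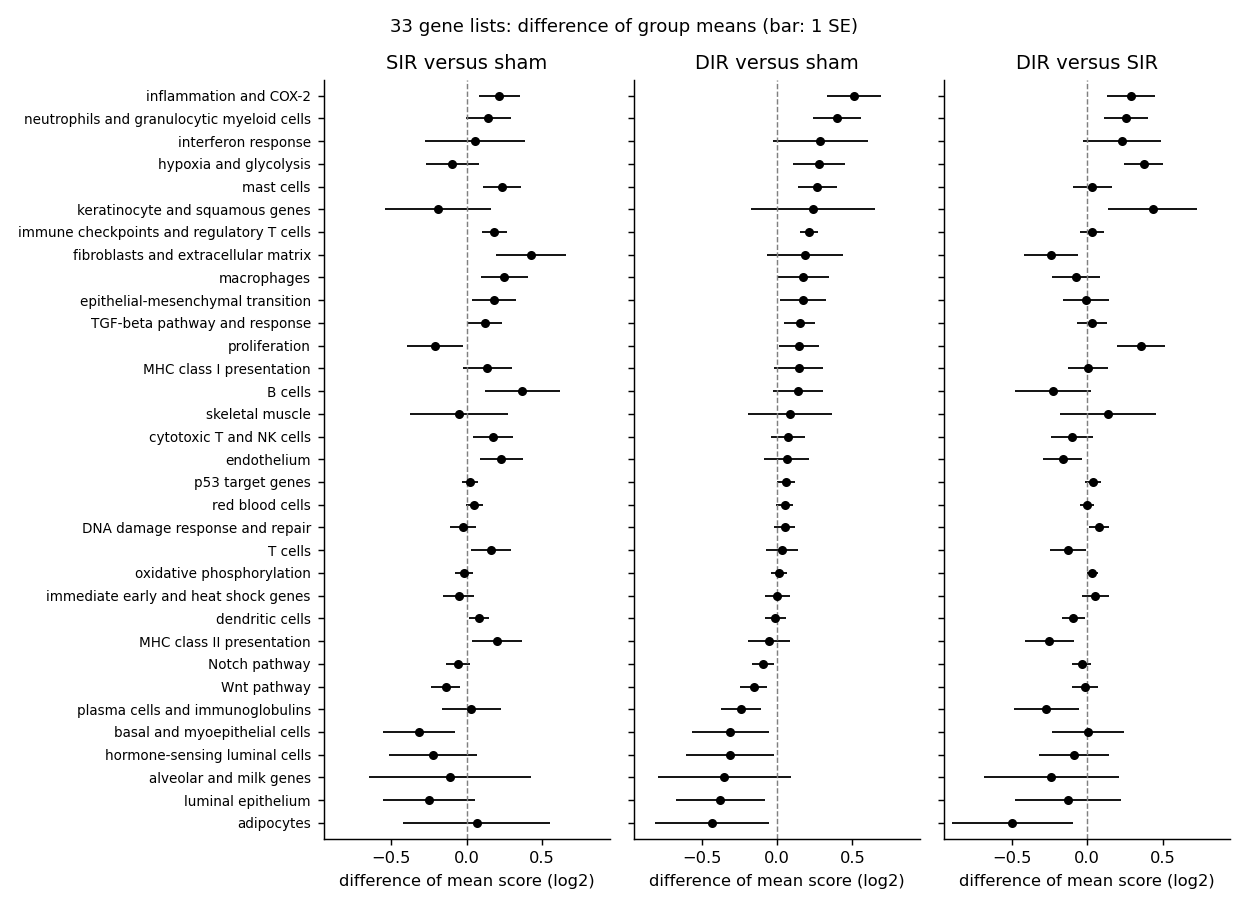
Difference of the mean score (horizontal axis, log2) for 33 gene lists in SIR versus sham, DIR versus sham and DIR versus SIR; points are differences of group means and bars 1 SE. In DIR versus sham the inflammation and COX-2 list had the highest difference, +0.51, and adipocyte genes the lowest, -0.43; no list passed in any of the 3 panels.

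The comparison of DIR with SIR tumours set densely against sparsely ionizing radiation. Dose differed as well (49 or 30 cGy in DIR, 10, 50 or 100 cGy in SIR), so radiation quality and dose cannot be separated. Hypoxia and glycolysis genes had higher means in DIR tumours, 21 of 22 above 0. Their score was 0.37 ± 0.13 (SE) higher, with 16 of 19 DIR tumours above the SIR mean, and did not pass (permutation p = 0.00666, adjusted 0.22). In this list 3 members rose when adjusted over the list alone: the glucose transporter Slc2a1 (GLUT1) by +0.51, the glycolytic enzyme Gapdh by +0.13 and the oxygen sensor Egln3 by +0.92, while the enzyme gene Pgam1 stood at +0.40. All 31 proliferation genes lay above 0 as well. Their score was 0.35 ± 0.16 (SE) higher (permutation p = 0.0161, adjusted 0.265; 16 of 19 tumours above the SIR mean), with the ribonucleotide reductase subunit Rrm2 at +0.59, the mitotic kinase Aurka at +0.51, topoisomerase Top2a at +0.46 and the kinase Melk at +0.37. Without SIR 2 the proliferation difference was +0.243. Within SIR the proliferation score rose with dose (slope +0.059 per 10 cGy, not passing), so the difference was smaller against the 50 and 100 cGy tumours. Mki67 stood at -0.011 with 50 and 100 cGy arrays only. Genes of MHC class II presentation lay on the other side of 0, 10 of 11 below 0, with the class II chains H2-Eb1 at -0.52 and H2-Ab1 at -0.48, the peptide loading subunit H2-DMb1 at -0.31 and its regulator H2-Ob at -0.20. Their score differed by -0.25 ± 0.16 (SE; permutation p = 0.119, adjusted 0.693; 13 of 19 tumours below the SIR mean), and by -0.16 without SIR 9. Lists of other tissue also differed without passing. Adipocyte genes (17 of 17 below 0) had the widest difference of the 33 lists, -0.50 ± 0.40 (SE), and -0.24 without SIR 2. Fibroblast and extracellular matrix genes (22 of 23 below 0) differed by -0.24 ± 0.18 (SE; -0.16 without DIR 6) and endothelial genes (20 of 22 below 0) by -0.16 ± 0.13 (SE; -0.10 without SIR 2). Keratinocyte and squamous genes (21 of 21 tested above 0) differed by 0.43 ± 0.30 (SE), with 9 of 19 DIR tumours above the SIR mean. The difference was 0.28 without DIR 3 and 0.27 without DIR 5. Each time the other tumour of this nearly identical pair remained, with scores of 3.00 and 3.10 (next DIR tumour 1.14). The squamous difference without both was not computed. The share of each tissue in the samples was not measured. It was not separated from changes within the tumour cells.

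No single gene passed between DIR and SIR, and all differences named here are values only. Those of smallest p on the higher side were the alpha-tubulin Tuba1b (+0.62), the nucleotide hydrolase Nudt2 (+0.36), the microRNA gene Mir16-2 (+0.31), Gm6408 (+0.24) and the mitochondrial lipid transfer protein gene Prelid1 (+0.20). On the lower side were Thnsl2 (-0.47), collagen Col28a1 (-0.38), the calcium channel Cacna1a (-0.33), the coenzyme Q kinase Coq8b (-0.32) and the germinal centre gene Gcsam (-0.30). Of the fixed genes, Cdkn1a stood at +0.54 with 16 of 19 DIR tumours above the SIR mean, Ptgs2 at +0.68, Esr1 at -0.43, Cd3e at -0.35, and Cd4 and Krt14 at -0.33 and +0.33. Closer to 0 stood Ly6g at +0.22, Adgre1 at -0.20, Csf1r at -0.20, Cd8a, Foxp3 and Mki67 at -0.15, -0.15 and +0.15, Krt8 at +0.14, Pgr at -0.08, Tgfb1 at +0.04 and Cd274 at -0.02. By limma 0 genes passed (smallest adjusted p = 0.891), and 988 had an unadjusted p under 0.05 (551 higher, 437 lower, 897 expected). Without moderation of the variances, in a fit to the arrays of both groups alone, 0 passed. Of the lists 0 of 33 passed by permutation, 2 had an unadjusted p under 0.05, and without DIR 15 there was 1 that passed, hypoxia and glycolysis. Over all lists 3 genes rose and 0 fell when adjusted over the list alone, against 0 when adjusted over all genes. The camera test called 16 lists at the preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.288, for hypoxia and glycolysis), and fry called 0 (smallest adjusted p = 0.253).

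Irradiated tumours were also compared with sham as a whole, single genes with equal weight for SIR and DIR and list scores as the mean over all 34 tumours. Gm13544 was lower than in sham tumours by a log2 difference of -0.89 ± 0.15 (SE), with 34 of 34 irradiated tumours below the sham mean (n = 34 against 9). However, sham 4, sham 6, sham 7 and sham 9 (6.11 to 6.17) lay within the irradiated range of 5.63 to 6.49. Below the threshold of significance stood Dlx3 at -1.86 (30 of 34 tumours), Map7d2 at -1.51 (34 of 34), Lrrn1 at -1.07 (33 of 34) and Pex3 at +0.49 (34 of 34), each with an adjusted p of 0.0904 by limma (0.125 with DIR 3 and DIR 5 averaged). Rbms2 stood at +0.43 and Arl1 at +0.30 (adjusted p = 0.111 and 0.123, 34 and 32 of 34 tumours). The checkpoint and regulatory T cell score was 0.20 ± 0.06 (SE) above sham (exact permutation p = 0.0115, adjusted 0.381; 28 of 34 tumours), with Tnfrsf9 at +1.01, Havcr2 at +0.52, Ikzf2 at +0.45 and Tnfrsf18 at -0.29. The inflammation score was 0.38 ± 0.14 (SE) above sham (exact permutation p = 0.0409, adjusted 0.655; 27 of 34 tumours), with Cxcl5 at +0.79, Ptges at +0.70, Nos2 at +0.69 and the cytokine Osm at +0.19. By limma 1 gene passed (Gm13544, log2 difference -0.89, adjusted p = 0.00447, 34 of 34 tumours), and 1568 genes had an unadjusted p under 0.05 (730 higher, 838 lower). Without moderation of the variances 1 passed, in a fit that pooled the 34 irradiated tumours in place of equal weight for SIR and DIR. The count was 30 without sham 4, 12 without sham 8, 11 without sham 7, 8 without sham 6 and 2 without DIR 15 or DIR 17. Of the lists 0 of 33 passed, with 2 at an unadjusted p under 0.05. Over all lists 2 genes rose and 5 fell when adjusted over the list alone, and 0 when adjusted over all genes. The camera test called 17 lists at the preset correlation, none of which held with an estimated correlation (smallest adjusted p = 0.815), and fry called 0 (smallest adjusted p = 0.611).

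Both comparisons against sham share the 9 sham arrays. Their log2 differences had a Pearson correlation of 0.766 across genes, which are not independent replicates, where simulated unchanged groups sharing the sham arrays gave 0.638 on average (central range of the draws 0.401 to 0.81). The covariance was 0.0395 against 0.0205 simulated (central range 0.00945 to 0.0367). With separate sham arrays for each comparison the correlation was 0.255 on average (lowest to highest draw -0.0784 to 0.467). The covariance there was 0.018 (lowest to highest draw -0.00654 to 0.0281). Both comparisons called the same gene, Gm13544 (calls in both, 1).

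Within DIR, tumours of silicon-exposed hosts were compared with those of argon-exposed hosts; ion and dose change together here and cannot be separated. Inflammatory genes had lower means in Si tumours, 20 of 23 below 0, with interleukin Il1a at -1.39, the attractants Cxcl5 at -1.21 and Cxcl1 at -1.02 and the cytokine Tnf at -0.54. The inflammation score differed by -0.52 ± 0.20 (SE) and did not pass (exact permutation p = 0.101, adjusted 0.861; 5 of 5 Si tumours below the Ar mean). T cell genes lay above 0 in 13 of 16 cases, with the T cell receptor component Cd3g at +0.89, the adaptor Lat at +0.39, the regulator Ubash3a at +0.26 and the surface receptor Cd6 at +0.20, and their score differed by +0.20 ± 0.15 (SE; exact permutation p = 0.167, adjusted 0.861; 3 of 5 tumours), and by +0.09 without DIR 15. The single genes of smallest p were the lymphocyte receptor Klrb1 (+0.34), the netrin receptor Unc5c (+0.91) and the tetraspanin Tspan9 (+0.77) on the higher side and the GTPase Rab24 (-0.35), the RNA gene Snhg4 (-0.53) and the nucleolar protein gene Nol8 (-0.36) on the lower. By limma 0 genes passed (smallest adjusted p = 1), 392 had an unadjusted p under 0.05 (207 higher, 185 lower), and 897 were expected. Of the lists 0 of 33 passed and 0 had an unadjusted p under 0.05, and 0 list genes passed adjusted over the list alone or over all genes. The camera test called 15 lists at the preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.625), and fry called 0 (smallest adjusted p = 0.816).

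Within SIR, the trend with gamma dose was tested over 15 tumours. Alveolar and milk genes had lower values at higher dose, all 18 with a slope below 0, and 8 of them fell when adjusted over the list alone. The beta-casein gene Csn2 had a mean log2 intensity of 11.14 ± 2.66 (SD, n = 7) at 10 cGy and 6.5 ± 1.17 (SD, n = 4) at 100 cGy, a slope of -0.51 ± 0.16 (SE) per 10 cGy, and the alpha-casein Csn1s1 had a slope of -0.52, the milk fat enzyme Xdh one of -0.16 and the milk fat globule protein gene Mfge8 one of -0.07. The list score had a slope of -0.23 ± 0.09 (SE) per 10 cGy and did not pass (exact permutation p = 0.0199, adjusted 0.435). Other lists lay on the same side without passing: luminal epithelium (22 of 23 genes below 0, slope -0.11, and -0.05 without SIR 15), adipocytes (17 of 17, slope -0.12, and -0.06 without SIR 2) and skeletal muscle (18 of 18 tested, slope -0.11, and -0.06 without SIR 4). At 10 cGy the tumours with the highest milk scores (SIR 7 at 2.98, SIR 1 at 2.42 and SIR 2 at 1.27) also had the highest adipocyte scores (1.51, 1.26 and 3.79). A different share of normal tissue was not separated from the dose. Among the lists on the other side of 0, proliferation had a slope of +0.059 (+0.033 without SIR 2). DNA damage response and repair had one of +0.029 (+0.02 without SIR 2), and neither passed. Neutrophil genes had a slope of -0.05 ± 0.02 (SE; exact permutation p = 0.0448, adjusted 0.435), led by lactoferrin Ltf at -0.40, which is also a milk protein, with the granule protein gene Ngp at -0.08, lipocalin Lcn2 at -0.17 and the histamine enzyme Hdc at -0.06. In that list 1 of 20 genes fell when adjusted over the list alone. Lcn2 stood apart on the low side in SIR 8 at 50 cGy (9.67, next 12.38) and SIR 15 at 100 cGy (8.6, next 12.06). Both tumours had low luminal scores, so the neutrophil slope was not separated from epithelial expression. Mast cell genes had a slope of -0.05 ± 0.02 (SE; exact permutation p = 0.0356, adjusted 0.435), with the proteases Mcpt8 and Mcpt4 both at -0.12, the transcription factor Gata2 at -0.03 and the prostaglandin synthase Hpgds at +0.05, and 1 of 7 fell when adjusted over the list alone.

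No single gene passed the dose trend over all genes. The nearest were the patched-domain gene Ptchd4, with a slope of +0.23 ± 0.03 (SE) per 10 cGy, and, on the lower side, the mesenchymal transcription factor Tbx15 (-0.23), the endotoxin co-receptor Cd14 (-0.20) and the secreted protein gene Scube1 (-0.21), each with a limma adjusted p of 0.054 and all 4 tumours at 100 cGy on the side of the slope from the 10 cGy mean. Morn4 had a slope of +0.17 (adjusted p = 0.0774) and Fam171b one of +0.19 (adjusted p = 0.159), again in 4 of 4 tumours. By limma 0 genes passed, 1650 had an unadjusted p under 0.05 (903 higher, 747 lower), and 897 were expected. The count was 4 with the stricter filter on low values or after repeated quantile normalization, and it was 7 without SIR 5, 6 without SIR 8, 4 without SIR 2, 2 without SIR 14 and 1 without SIR 9. Of the lists 0 of 33 passed, with 3 at an unadjusted p under 0.05. Over all lists 0 genes rose and 13 fell when adjusted over the list alone, against 0 when adjusted over all genes.

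**Figure D3:**
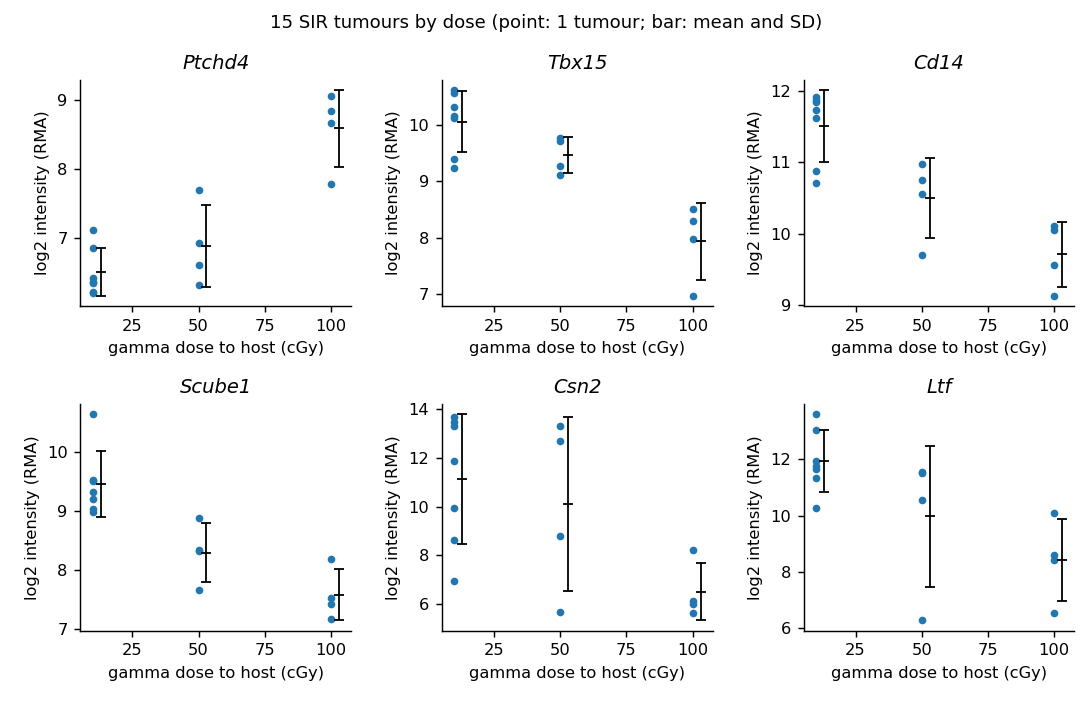
Log2 intensity (vertical axis, RMA values) of 6 genes against the gamma dose to the host (horizontal axis, cGy) in the 15 SIR tumours; points are tumours and bars the mean and SD at each dose. Cd14 had a mean of 11.51 at 10 cGy and 9.71 at 100 cGy, and Csn2 one of 11.14 and 6.5; no gene passed over all genes.

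The title of the series links the growth of the tumours to the pattern of immune cells in them, and growth rates were not analysed here. Over all 43 tumours, after subtraction of group means, the proliferation score was set against 13 immune scores. Tumours with higher proliferation scores had lower scores for MHC class II presentation (Pearson r = -0.422, permutation p = 0.00528, adjusted 0.0686; Spearman rho = -0.447, permutation p = 0.00304, adjusted 0.0229), T cells (r = -0.371, p = 0.0159, adjusted 0.0688; rho = -0.43, p = 0.00422, adjusted 0.0229) and dendritic cells (r = -0.372, p = 0.0143, adjusted 0.0688; rho = -0.42, p = 0.00529, adjusted 0.0229), by permutation. These 3 of 13 relations passed by rank and 0 of 13 passed by Pearson r. Macrophage scores showed no such relation (r = 0.113, permutation p = 0.467, adjusted 0.606; rho = 0.106, permutation p = 0.502, adjusted 0.583). For each list, the 2 tumours farthest from its own median score were then left out, so the tumours left out could differ between lists. There r was -0.381 for MHC class II, -0.349 for T cells and -0.397 for dendritic cells (permutation adjusted p = 0.0546, 0.0574 and 0.0546). By rank, dendritic cells passed (rho = -0.455, adjusted 0.0278). T cells (-0.372, adjusted 0.0538) and MHC class II (-0.386, adjusted 0.0538) no longer did. MHC class I presentation passed by rank there (-0.44, adjusted 0.0278). With the fibroblast and extracellular matrix score partialled out, 5 of 13 relations passed by rank and 0 by Pearson r. These were MHC class II (rho = -0.487, adjusted 0.0144), dendritic cells (-0.455, adjusted 0.0156), T cells (-0.421, adjusted 0.0215), checkpoints and regulatory T cells (-0.404, adjusted 0.0233) and MHC class I (-0.383, adjusted 0.03). Within groups, r for MHC class II was -0.434 in sham, -0.425 in SIR and -0.444 in DIR tumours, with sampled permutation adjusted p of 0.656, 0.24 and 0.373 and rho of -0.483, -0.461 and -0.361. With SIR 2, a tumour of high adipocyte score, left out, a choice made after its scores were seen, 4 of 13 relations passed by Pearson r, those of T cells, checkpoints and regulatory T cells, dendritic cells and MHC class II.

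**Figure D4:**
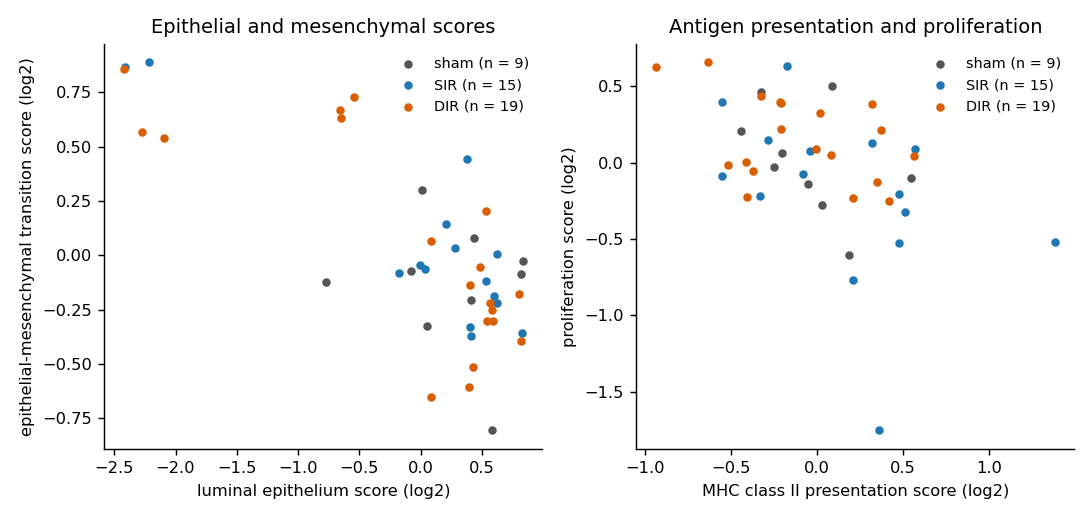
Scores per tumour (log2, each the mean over a gene list relative to all tumours) for sham (n = 9), SIR (n = 15) and DIR (n = 19): left, luminal epithelium against epithelial-mesenchymal transition; right, MHC class II presentation against proliferation. In the left panel 5 irradiated tumours lie at luminal scores from -2.42 to -2.1, and the next tumour is at -0.77.

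The spread of the scores between tumours was also compared, since a pattern found in part of the irradiated tumours would widen it. Of the 33 lists 26 had a wider spread in irradiated than in sham tumours and 7 a narrower one. By permutation 0 lists passed (smallest adjusted p = 0.357) and 1 had an unadjusted p under 0.05.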

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

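Tumours were singled out where the highest or lowest value of a group of 4 to 9 stood apart by Dixon's ratio of gap to range; chance alone does this in about 1 in 20 groups, and of 314 sets of values 23 did, where 16 were expected. Of the tests in this part, both on the tumours of low luminal score were chosen after the result was seen.

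Among sham tumours, sham 9 had a score for keratinocyte and squamous genes of 2.43, the other 8 lying between -0.72 and 0.05. The same tumour had the highest log2 intensity of the B cell genes Cd22 (8.13, next 7.61) and Bank1 (8.51, next 7.13), of the cell cycle inhibitor Cdkn1a (12.1, next 10.76) and of the ligand Wnt10a (8.91, next 7.98). Sham 3 had 9.68 for Bex2 (next 7.21) and sham 2 had 8.32 for the nitric oxide synthase Nos2 (next 7.46), while sham 6 had 7.98 for the Wnt receptor Lgr6 (next 10.0). Among the 5 Si tumours, DIR 19 had a luminal score of -2.42 (others 0.09 to 0.8) and a red blood cell score of 0.17 (others -0.05 to -0.01), and DIR 15 a TGF-beta score of -0.38 (others 0.15 to 0.33). At 10 cGy, SIR 2 had a proliferation score of -1.75 (next -0.53) and an inflammation score of -0.60 (next -0.17). SIR 5 had a squamous score of 0.51 (next -0.20) and a casein Csn1s1 intensity of 7.4 (next 10.74), and SIR 6 one of 10.64 for Scube1 (next 9.53). At 50 cGy, SIR 8 had a luminal score of -2.22 (others 0.28 to 0.41) and a lipocalin Lcn2 intensity of 9.67 (next 12.38), SIR 10 a p53 target score of -0.09 (next -0.02), and SIR 11 an intensity of 8.28 for Morn4 (next 7.06). At 100 cGy, SIR 15 had an epithelial-mesenchymal transition score of 0.87 (next -0.05), an Lcn2 intensity of 8.6 (next 12.06) and an Hpgds intensity of 9.96 (next 8.44).

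Gm13544 lay above the highest of 34 irradiated tumours (6.49) in 5 of 9 sham tumours, sham 1 (7.87), sham 5 (7.85), sham 3 (7.6), sham 8 (7.42) and sham 2 (6.97), while the other sham tumours lay between 6.11 and 6.17. Nerve tissue in the sham samples is a candidate source, but the score of 14 nerve markers was only 0.036 ± 0.074 (SE) higher in sham than in irradiated tumours (exact permutation p = 0.576), with the myelin gene Mbp at 8.08 and 7.86 and the synaptic gene Snap25 at 6.31 and 6.39, which argues against it. In all 10 genes had their 5 highest values in sham tumours, and 3 of 100 splits of the same arrays, the real one included, gave as many (highest other split 17). The number 5 was taken from Gm13544 itself, so this test decides nothing, and chance among many genes stays open. Array handling was not tested, since no batch is given, and an effect of host irradiation stays open as an untested hypothesis that may apply to some tumours only.

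In 5 irradiated tumours (SIR 8, SIR 15, DIR 1, DIR 7 and DIR 19) luminal scores lay between -2.42 and -2.1, with the adhesion gene Epcam at 6.36 to 7.66 against 10.34 to 12.3 in the other tumours, E-cadherin Cdh1 at 7.58 to 7.97 against 10.44 to 12.03, the splicing factor Esrp1 at 6.13 to 6.48 against 9.16 to 11.01 and the mesenchymal factor Zeb1 at 9.22 to 9.74 against 6.61 to 8.91. Other genes overlapped, among them the luminal keratins Krt8 (9.91 to 11.69 against 9.89 to 12.94) and Krt18 (8.79 to 11.02 against 10.36 to 12.94), the claudin Cldn3 (8.02 to 11.38 against 9.99 to 12.83) and the mesenchymal factors Snai2 (9.86 to 11.13 against 8.17 to 12.56) and Twist1 (8.88 to 9.77 against 6.9 to 10.22). Unlike Cldn3, the claudins Cldn4 (7.16 to 7.35 against 8.5 to 12.73) and Cldn7 (6.21 to 7 against 7.09 to 10.64) lay below all other tumours. A smaller share of tumour cells is a candidate explanation. The proliferation score averaged 0.229 ± 0.093 (SE, n = 5), but it does not measure that share. Of 13 lists of other cell types 3 lay below 0, among them plasma cells at -0.36. Most lay above 0, with macrophages at 0.80, fibroblasts and extracellular matrix at 0.45 and endothelium at 0.27. These values point both ways, so a smaller share of tumour cells stays open. The placing of these tumours, 5 of 34 irradiated and 0 of 9 sham, gave a Fisher exact p of 0.566; as the most extreme placing towards irradiated hosts it could not have passed, so the test decides nothing and chance stays open. A tumour type with part of the epithelial traits lost stays open as a hypothesis, and no biological explanation was tested.

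DIR 3 and DIR 5, both from Ar-exposed hosts, differed over the tested genes with an SD of 0.177, against 0.364 in the next closest of 903 pairs and a median of 0.646. That SD was 0.597 times the one over 4246 genes below the filter, where the median pair had 1.687 and the next lowest 0.906, which is consistent with RNA of 1 tumour on both arrays. Separate tumours of one squamous type are a candidate explanation too and stay open: DIR 3 and sham 9, also of high squamous score, differed 3.71 times as much, about as much as the median pair, so sham 9 does not show how far such tumours lie apart. Whether the same tumour was sampled from a single host or a label was exchanged was not tested. Averaged as 1 tumour, the pair left the counts of genes at an adjusted p under 0.05 unchanged (0 for DIR versus SIR and Si versus Ar, 1 for each comparison with sham), while the number under 0.1 went from 25 to 1 in DIR versus sham and from 5 to 1 in all irradiated versus sham, with Gm13544 at -0.86 in DIR versus sham.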

How the results depend on the processing

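The settings with DIR 3 and DIR 5 averaged, with SIR 2 left out and with the 5 tumours of low luminal score left out were chosen after the result was seen; the others were planned. Of 10099 values of single genes and lists under alternatives, 9897 kept their direction and their side of the threshold, 126 moved past it, 31 no longer passed and 45 reversed. Apart from Gm13544 none of these genes and lists had passed. A value that failed again with its sign kept counted as unchanged, so the high number says little about robustness. Of the counts and summary values, 124 stayed within 1.5 times the reported value (or within their spread) and 34 did not, the omission of single arrays aside. Gm13544 lay below sham in SIR and in DIR under each setting that tested it, between -1.01 and -0.79 in SIR and between -0.98 and -0.76 in DIR when each array was left out. The number of genes passing was fragile, and unless stated below the cause was not tested.

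The stricter filter gave 0 genes in SIR versus sham, DIR versus sham and all irradiated versus sham, because it removed Gm13544 itself, and 4 with gamma dose, where fewer genes were tested. With no filter all irradiated versus sham had 2 genes. Testing every probe set gave 0 for SIR versus sham, since more tests were corrected for. Quantile normalization again gave 4 genes with dose. Array weights gave 23 for DIR versus sham, 10 for all irradiated and 3 with dose. With the first principal component as a covariate, 223 genes passed in DIR versus sham and 62 in all irradiated versus sham; the component was taken from residuals, so that it lowers the residual spread by construction. Without moderation, fitted to the arrays of both groups only, SIR versus sham and DIR versus sham had 0 genes. With moderation in those arrays both also had 0 genes, so the part of moderation was not separated. With fewer samples, SIR versus sham had 0 genes with 10 cGy arrays only and 0 with 50 and 100 cGy arrays only, and DIR versus sham had 0 with Ar only and 0 with Si only. Without the 5 tumours of low luminal score both had 0.

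The replicate block gave 0 genes for SIR versus sham, 2 for DIR versus sham and 3 for all irradiated versus sham. The 2 in DIR versus sham were Ackr3 and Dlx3, named after their values were seen, and Gm13544 was lost there. The numbers do not pair the samples: of 33 same-numbered pairs 3 had a correlation over 0.1, with a median of -0.088 and a range of -0.302 to 0.438. Under the block Krt14 (-0.305), Cd8a (-0.036) and Ly6g (0.025) reversed in SIR versus sham; the cause was not tested.

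Of the lists, 1 passed in DIR versus sham after quantile normalization again and 1 after subtraction of the array median, that of checkpoints and regulatory T cells in both. The camera test with a preset correlation called 12 lists in SIR versus sham, 10 in DIR versus sham, 16 in DIR versus SIR, 17 in all irradiated versus sham and 15 in Si versus Ar; it assumes a correlation of 0.01 between genes of a list, and with an estimated one it called 0. With SIR 2 left out 4 immune lists were related to proliferation by Pearson r. The correlation of both comparisons with sham was 0.255 on average (lowest to highest draw -0.0784 to 0.467) with separate sham arrays. That setting ends the sharing and also leaves 4 or 5 sham arrays to each. Their parts in the fall of the correlation were not separated.

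Leaving out each array in turn gave 0 to 1 genes for SIR versus sham, 0 to 86 for DIR versus sham, 1 to 30 for all irradiated versus sham and 0 to 7 with dose. It gave 0 to 1 lists for DIR versus sham and 0 to 1 for DIR versus SIR. SIR versus sham had 0 genes without sham 1, 2, 3, 5 or 8 or SIR 1, 3, 4, 6, 9, 10, 11, 13 or 15. DIR versus sham had 0 without sham 1, 2, 3 or 5 or DIR 5, 86 without sham 4, 17 without sham 8, 14 without sham 7, 11 without sham 6, 3 without sham 9 or DIR 15 and 2 without DIR 17. All irradiated versus sham had 30 without sham 4, 12 without sham 8, 11 without sham 7, 8 without sham 6 and 2 without DIR 15 or DIR 17. Dose had 7 without SIR 5, 6 without SIR 8, 4 without SIR 2, 2 without SIR 14 and 1 without SIR 9. For lists, 1 passed in DIR versus sham without DIR 11, DIR 13 or sham 4, and 1 in DIR versus SIR without DIR 15.

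Small differences of the fixed genes reversed, none of which had passed. With 50 and 100 cGy arrays only, Esr1 (-0.163) and Krt14 (-0.023) in SIR versus sham and Mki67 (-0.011) and Cd274 (0.165) in DIR versus SIR did so. With 10 cGy arrays only it was Cd8a (-0.139) and Ly6g (0.079) in SIR versus sham, and with array weights Cd274 (0.008) in DIR versus SIR. With Si arrays only it was Cd3e (0.229), Cd4 (-0.004), Cd8a (0.144) and Foxp3 (0.007) in DIR versus sham. Without the 5 tumours of low luminal score it was Adgre1 in DIR versus sham (-0.04) and Pgr in DIR versus SIR (0.04). Over the arrays left out, Esr1 ran from -0.001 to 0.304, Krt14 from -0.199 to 0.246, Cd8a from -0.059 to 0.108 and Ly6g from -0.166 to 0.078 in SIR versus sham. Cd3e ran from -0.194 to 0.031 in DIR versus sham, and Pgr from -0.287 to 0.101, Cd274 from -0.115 to 0.049 and Tgfb1 from -0.005 to 0.083 in DIR versus SIR. The causes were not tested. Signal over background limits what an array shows of weakly expressed genes, and Gm13544 lay near the filter value of 5.98 in irradiated tumours.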

Other observations

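The tests against other splits of the arrays were planned, and the descriptions of single tumours were chosen after the result was seen. By limma, chance could not be excluded for the number of genes in the comparisons with sham, though SIR versus sham lay at the limit of 5 in 100 only with the real split counted (4 others called any gene). With the real split included, as many genes came from 5 of 100 splits for SIR versus sham (real 1, highest other 7), 9 for DIR versus sham (real 1, highest other 12) and 8 for all irradiated versus sham (real 1, highest other 33). For DIR versus SIR, Si versus Ar and gamma dose the real count was 0 (988, 392 and 1650 genes at an unadjusted p under 0.05), which each of 100 splits reaches by definition (highest others 7, 61 and 87), so that this count tests nothing there. At an unadjusted p under 0.05, again with the real split included, 5 of 100 splits gave as many genes as the 2014 of DIR versus sham (median of the others 828, highest 3143), 34 as many as the 982 of SIR versus sham (median 763, highest 2557) and 8 as many as the 1568 of all irradiated versus sham (median 824, highest 2144). For DIR versus SIR 43 gave as many as the real 988 (median 866, highest 3150), for Si versus Ar 90 as many as 392 (median 765, highest 2820) and for gamma dose 11 as many as 1650 (median 782, highest 2760). Splits that call several times the real count point to a structure of the samples or to genes that vary together, and which of these applies was not tested.

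The other lists did not pass in DIR versus sham by exact permutation. Score differences (± SE) were 0.28 ± 0.17 for hypoxia and glycolysis, 0.14 ± 0.13 for proliferation, 0.17 ± 0.17 for macrophages, 0.14 ± 0.17 for B cells and -0.05 ± 0.14 for MHC class II presentation. They were -0.31 ± 0.29 for hormone-sensing luminal cells, -0.15 ± 0.09 for the Wnt pathway, 0.19 ± 0.25 for fibroblasts and extracellular matrix and 0.07 ± 0.15 for endothelium. Further values were 0.07 ± 0.11 for cytotoxic T and NK cells, -0.24 ± 0.13 for plasma cells, -0.01 ± 0.07 for dendritic cells, 0.14 ± 0.16 for MHC class I presentation and 0.29 ± 0.32 for the interferon response. Luminal epithelium differed by -0.38 ± 0.30, alveolar and milk genes by -0.35 ± 0.44, keratinocyte and squamous genes by 0.24 ± 0.41 and epithelial-mesenchymal transition by 0.17 ± 0.15. The TGF-beta pathway differed by 0.15 ± 0.10, the Notch pathway by -0.09 ± 0.07 and DNA damage response and repair by 0.05 ± 0.07. Values for other tissues and processes were -0.43 ± 0.38 for adipocytes, 0.09 ± 0.28 for skeletal muscle, 0.05 ± 0.06 for red blood cells, 0.02 ± 0.05 for oxidative phosphorylation and 0.00 ± 0.08 for immediate early and heat shock genes. Of the differences over 0.1, single tumours moved several by more than 1.5 times. The proliferation difference was 0.07 without sham 7, that of macrophages 0.10 without DIR 7, that of B cells 0.04 without DIR 8 and 0.24 without sham 9, and that of the Wnt pathway -0.10 without sham 9. The hormone-sensing difference was -0.21, -0.20 and -0.18 without sham 1, sham 7 and sham 8, and the fibroblast difference 0.32, 0.09 and 0.11 without sham 2, sham 4 and sham 5. MHC class I stood at 0.08 without sham 3 and 0.24 without sham 4. The luminal difference was -0.25 without DIR 19, the milk gene difference -0.02 without sham 8, and the interferon difference 0.17 without sham 3 and 0.48 without sham 4. The adipocyte difference was -0.25 without sham 6 and -0.28 without sham 8, and that of epithelial-mesenchymal transition 0.09 without sham 4. The squamous difference was 0.09 without DIR 3, 0.08 without DIR 5, 0.16 without sham 4 and 0.55 without sham 9. DIR 3 and DIR 5, nearly identical, were left out singly only, so the squamous difference without the pair is not known.

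Single tumours stood out in list scores, which do not measure the share of a tissue. SIR 2 had an adipocyte score of 3.79, where SIR 9 came next at 1.85. SIR 9 had the highest scores for B cells (2.54), plasma cells (1.69), MHC class II presentation (1.38) and T cells (1.13). SIR 4 had a skeletal muscle score of 2.77, where DIR 12 came next at 1.87. The milk gene score was 2.98 in SIR 7 and 2.79 in sham 8, and the hormone-sensing luminal score was 1.93 in DIR 17 and 1.40 in SIR 14. DIR 3 and DIR 5 had squamous scores of 3.00 and 3.10.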
